A study of Rattus norvegicus with 294 samples.

How the data were processed

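Affymetrix rat expression arrays of laser-captured osteoblasts, lining cells and osteocytes from the vertebrae of ovariectomized rats were analysed. The deposited values are RMA signals on a linear scale in the unit intensity per the labels and the values themselves, and the labels name Affymetrix Expression Console, R 3.0.1, RMA and affy 1.38.1 with no roles. Values ran from 2.94 to 28282, and their log2 was taken before the tests, since the plan written earlier had taken them for log2 values. The 3 cell types have different quantiles and so appear to have been normalized apart, and how replicates were made is not given in the sources used here.

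The matrix held 31042 probe sets, of which 21262 were listed with genes, 20826 with 1 gene and 436 with several, and 9780 had no listed gene. Each of 14217 genes was represented by the probe set with the highest mean (4525 genes had several), with 20758 symbols taken from the gene table by ID. Genes were kept where the value was above the median of its array in at least 5 arrays of the fit. The tools were R 4.3.3, limma 3.58.1, statmod 1.5.0 and data.table (1.17.8). All arrays of a cell type were fitted with 1 mean per treatment and day, so that 20 groups share the spread, with the response between cell types from a fit of all arrays and the cell types in vehicle from a fit with day. Contrasts against vehicle, between doses (50 minus 3 mg/kg over the dosing days), over time (the response of day 183 minus that of day 8) and between cell types used moderated t and Benjamini-Hochberg adjusted p under 0.05. Groups held 3 to 5 arrays, which sets the precision, and signal over background per array is not given in the sources used here.

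Before the data were examined, 24 gene lists and the rule for the genes to name were fixed. The lists were Wnt antagonist and feedback genes, Wnt target genes, bone matrix genes, collagen synthesis enzymes, osteoblast differentiation genes, osteocyte markers, osteoclast regulators, TGF-beta and BMP genes, secretory pathway genes, ribosome biogenesis genes, p53 target genes, cell cycle genes, interferon response genes, immediate early and heat shock genes, osteoclast markers, erythroid markers, granulocyte markers, macrophage markers, B-lineage markers, endothelial markers, adipocyte markers, megakaryocyte markers, chondrocyte markers and skeletal muscle markers. They were tested with limma's camera at a preset correlation of 0.01 and again with the correlation estimated from the data, with adjusted p over all lists and contrasts of a family. Members that another list also holds were Wnt antagonist and feedback genes 1 of 16, Wnt target genes 4 of 22, osteoblast differentiation genes 2 of 25, osteocyte markers 5 of 22, osteoclast regulators 2 of 19, TGF-beta and BMP genes 3 of 28, secretory pathway genes 2 of 31, endothelial markers 1 of 15 and megakaryocyte markers 1 of 9, and the other lists shared none. By the rule, the 4 largest rises and 3 largest falls of each cell type and dosing day with the same sign at both doses, the 3 largest of each direction per comparison after dosing, the 8 largest per cell type pair, the 4 largest per dose, time and response contrast, up to 4 called members per list and 25 fixed genes were to be named, and the text prints a part of them to save space, chosen after their values were seen. Left out were some calls that other settings ended. Shared higher genes of osteoblasts and osteocytes on day 8 were named after their values were seen. Numbers of shared genes compare contrasts with different vehicle arrays, and independent lists would share the product of their sizes over the genes tested in both.

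Signal range is the 90th minus the 50th percentile of the log2 values of all probe sets of an array, and Dixon's 95% critical values set arrays apart in it. The marrow marker score is the mean log2 value of 30 erythroid, granulocyte and B-lineage markers tested in all 3 cell types, centred on its mean over all arrays. Alternatives were no filter, quantile normalization of the arrays of a fit, the mean of probe sets per gene, limma array weights, only the compared groups in the fit, the signal range as covariate, the arrays of outlying signal range left out, a replicate block by array order, and each array left out in turn. Labels were exchanged within cell type and day in 100 splits per result (seed 20). In simulations with 50 changed genes per size, limma recovered 26, 22, 16 and 48 at a log2 change of 0.5 and 48, 49, 49 and 50 at 1, in osteoblasts on day 85, lining cells on day 8, osteocytes off 50 mg/kg day 237 and osteoblasts 50 minus 3 mg/kg. Unchanged genes were 5.03, 5.67, 5.43 and 4.64% of the calls, which real arrays need not share. The labels do not name the rat, so arrays were not paired, and independent lists and fits over cell types leave out rats with several captures. Probe sets without a single listed gene were left out.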

Results

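The data were microarray profiles of vertebral bone cells from ovariectomized rats given vehicle or an antibody against sclerostin, the osteocyte protein that holds back Wnt signalling and bone formation. Laser capture gave material enriched for osteoblasts (97 arrays), lining cells (100 arrays) and osteocytes (97 arrays). Arrays of vehicle rats (120) stood beside 174 arrays of rats dosed weekly with 3 or 50 mg/kg, taken on days 8, 29, 85 and 183 of dosing or after dosing had stopped on day 183: 3 mg/kg on days 197 and 267, and 50 mg/kg on days 237 and 309. The 60 groups held 5 arrays each, except for 4 in osteoblasts at 3 mg/kg on day 8 and at 50 mg/kg on days 85 and 237, 4 in osteocytes at 3 mg/kg on day 29 and 3 in osteocytes at 50 mg/kg on day 85, and the number of arrays limits the precision. Changes are given as log2 fold changes with the standard error (SE), limma's adjusted p and the number of treated arrays on that side of the vehicle mean of the day. Gene lists have the mean log2 fold change and camera's adjusted p, and where a call ended on leaving out 1 array the arrays or their number are given.

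**Figure D1:**
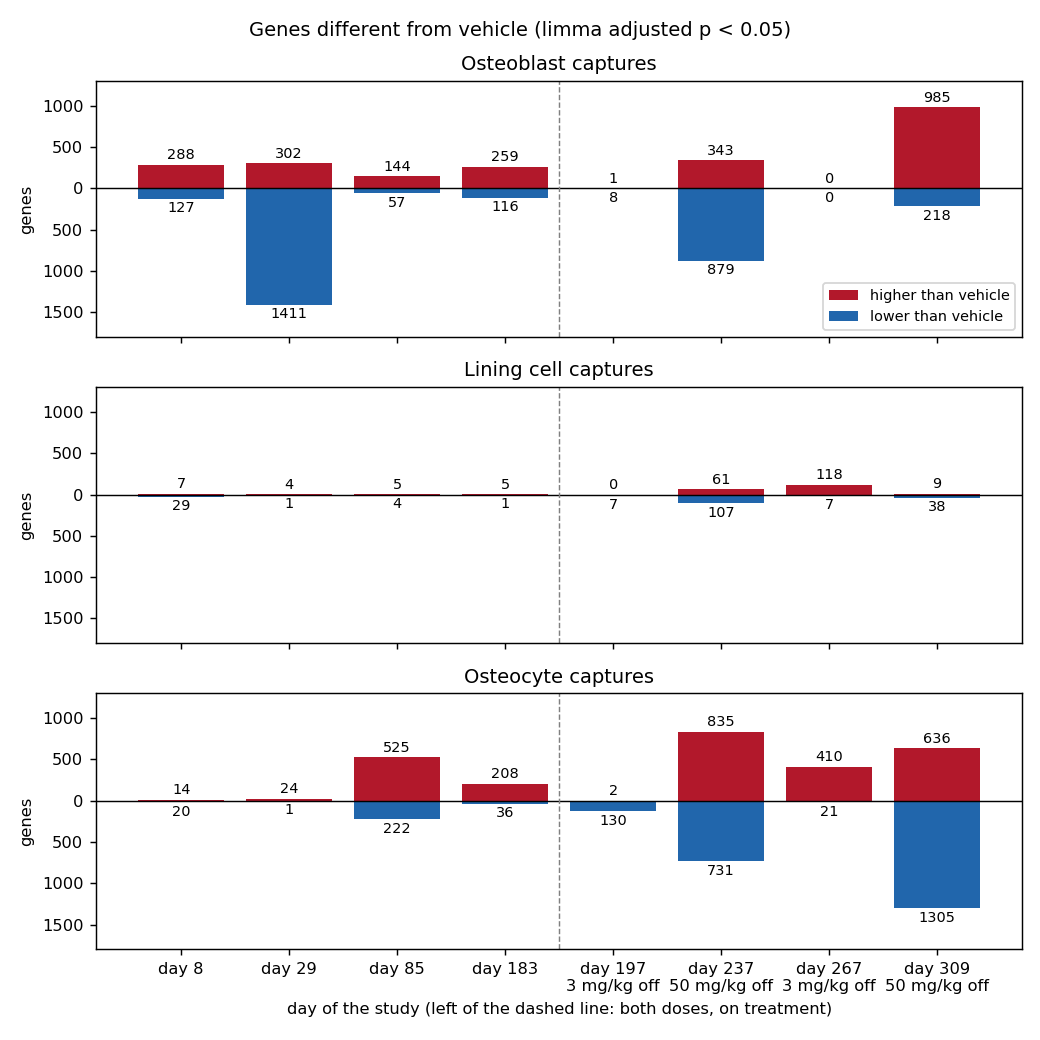
Genes higher (upward bars) and lower (downward bars) than vehicle at an adjusted p under 0.05 by limma, for each captured cell type and each day on treatment or after withdrawal. Osteocytes had 1566 such genes on day 237 and 1941 on day 309 after 50 mg/kg.

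Vehicle arrays answered which genes set the 3 captured cell types apart without antibody. Osteocytes stood out for Mepe, a mineralization regulator of osteocytes, which differed between osteoblasts and osteocytes by -4.55 (SE 0.18, adjusted p = 7.16e-48, 40 of 40) and between lining cells and osteocytes by -4.91 (SE 0.18, adjusted p = 2.84e-50, 40 of 40). Dmp1, needed for osteocyte maturation, differed by -3.16 and -4.32 in these pairs, and Spp1, Fgfr1, Thbs4 and Slit2 were also lower in osteoblasts than in osteocytes (-2.51, -2.21, -2.09 and -2.08). Osteoblasts exceeded lining cells in bone matrix products, by 2.51 for Col11a2 (SE 0.10, adjusted p = 2.92e-44, 40 of 40). Bglap (2.12), Cthrc1 (2.03), Col1a1 (2.01), Col1a2 (1.93), Col5a2 (1.77) and Sparc (1.73) followed. Quantile normalization left 23 of 27 bone matrix genes lower and 1 higher in osteoblasts than in osteocytes. Ctsk and Acp5, osteoclast enzymes, were lower in osteoblasts than in lining cells (-0.54 and -0.46). Osteoblasts and lining cells exceeded osteocytes in the platelet and endothelial genes Selp (3.03 and 2.57), Vwf (2.84 and 2.45) and Treml1 (2.82 and 2.25). Lining cells also did in Alox12 (2.46).

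The deposited values carried a shift of all genes between cell types. Its median was 0.42 for osteoblasts minus lining cells, 0.67 for osteoblasts minus osteocytes and 0.27 for lining cells minus osteocytes. Unnormalized changes and calls include it. limma called 11239, 11481 and 9561 of 11854 genes in these pairs, 11221, 11126 and 8484 higher and 18, 355 and 1077 lower. After quantile normalization, which removes the shift, 1976, 3805 and 3677 were higher and 1991, 3758 and 3262 lower. In lining cells minus osteocytes, of the 24 tested osteoblast differentiation genes 3 were higher, 19 lower and 2 did not pass (3 and 19 adjusted over the list alone, mean -0.97, adjusted p = 8.99e-28, adjusted p = 2.25e-07 with an estimated correlation). The normalized arrays gave 0 higher and 20 lower of 24 in that list. In the same pair, among the 9 tested megakaryocyte markers, 9 were higher, 0 lower and 0 did not pass (9 and 0 adjusted over the list alone, mean 1.99, adjusted p = 4.39e-19, adjusted p = 0.0151 with an estimated correlation). In osteoblasts minus osteocytes, of the 10 tested chondrocyte markers 3 were higher, 4 lower and 3 did not pass (3 and 4 adjusted over the list alone, mean 0.02, adjusted p = 0.000156, adjusted p = 0.0468 with an estimated correlation, a test that ran against the sign of the mean). The normalized arrays gave 1 higher and 8 lower of 10 there. Of the 30 list calls between cell types 19 held with an estimated correlation, 11 did not, and in 12 the mean or median had the opposite sign to the test, which ranks a list against the other genes.

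Comparisons with vehicle during dosing asked how each cell type responded to the antibody over time, with both doses weighted equally. On day 8 in osteoblasts Lox, the enzyme that crosslinks collagen, rose by 1.32 (SE 0.22, adjusted p = 0.000164, 9 of 9). Omd, a matrix proteoglycan of mineralizing bone, rose by 1.29 (SE 0.25, adjusted p = 0.00102, 9 of 9). Car1, a carbonic anhydrase of red cells, rose by 1.42 (SE 0.25, adjusted p = 0.000316, 8 of 9), and Rpl14, a ribosomal protein, by 1.13. Slc22a3 fell by 1.26 (SE 0.22, adjusted p = 0.000316, 9 of 9), with falls of Cfap100, a cilium protein, and Pcp4l1 (-1.32 and -1.17). Among the 33 tested cell cycle genes, 4 rose, 0 fell and 29 did not pass (13 and 0 adjusted over the list alone, mean 0.31, adjusted p = 4.4e-07, adjusted p = 0.351 with an estimated correlation). Of the 30 tested ribosome biogenesis genes 5 rose, 0 fell and 25 did not pass (8 and 0 adjusted over the list alone, mean 0.26, adjusted p = 0.000128, adjusted p = 0.351 with an estimated correlation). Of 11 erythroid markers 5 rose. The marrow marker score was 0.50 in vehicle, 0.61 at 3 mg/kg and 0.69 at 50 mg/kg. limma called 415 of 11412 genes, 288 higher and 127 lower, against 138 without vehicle replicate 3, and 78 with the compared groups alone and 760 with array weights. Calls ended with the compared groups alone (Lox) or quantile normalization (Pcp4l1) and on leaving out 1 array (Pcp4l1 for 6 of 14).

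In osteoblasts of day 29 Smoc2, a calcium-binding matrix protein, rose by 1.49 (SE 0.32, adjusted p = 0.00126, 9 of 10), and Col11a2, a fibrillar collagen, rose by 1.41 (SE 0.25, adjusted p = 0.000221, 9 of 10). Igfbp5, which binds insulin-like growth factors in bone, rose by 1.39 (SE 0.28, adjusted p = 0.000633, 10 of 10). Stat3 rose by 1.381, Col1a1 by 1.14 and Ccn4, a Wnt-induced secreted protein, by 0.76. Postn, a matrix protein of periosteum, fell by 1.39 (SE 0.32, adjusted p = 0.00219, 10 of 10), Ect2, which drives cytokinesis, fell by 1.25 (SE 0.23, adjusted p = 0.000351, 9 of 10), and the Wnt target Lef1 fell by 0.71 (SE 0.21, adjusted p = 0.0164, 9 of 10). Among the 33 tested cell cycle genes, 0 rose, 16 fell and 17 did not pass (0 and 19 adjusted over the list alone, mean -0.38, adjusted p = 3.73e-06, adjusted p = 0.42 with an estimated correlation). Of the 7 tested chondrocyte markers 1 rose, 0 fell and 6 did not pass (1 and 0 adjusted over the list alone, mean 0.38, adjusted p = 0.00495, adjusted p = 0.214 with an estimated correlation). The signal range of these arrays moved with dose, with means of 3.53 in vehicle, 3.41 at 3 mg/kg and 3.16 at 50 mg/kg, and the marrow marker score was 0.62, 0.52 and 0.40. limma called 1713 of 11412 genes, 302 higher and 1411 lower (444 and 690 after quantile normalization), against 687 without vehicle replicate 2. With the signal range as covariate it was 191. In osteoblasts of day 29 calls ended with quantile normalization (Lef1), with the mean of probe sets (Lef1, Col1a1), with the signal range covariate (Lef1, Col1a1, Ccn4, chondrocyte markers) and on leaving out 1 array (Lef1 for vehicle replicates 1 and 2, Col1a1 for vehicle replicates 1 and 2). Stat3 was 0.74 without vehicle replicate 1.

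On day 85 in osteoblasts Col1a1, the main collagen chain of bone, rose by 1.89 (SE 0.36, adjusted p = 0.00126, 9 of 9), with 1.37 at 3 mg/kg and 2.41 at 50 mg/kg. Col11a1, another fibrillar collagen, rose by 1.64 (SE 0.38, adjusted p = 0.0123, 9 of 9), and Cthrc1, a secreted protein of collagen-making cells, rose by 1.57 (SE 0.32, adjusted p = 0.00255, 9 of 9). Thbs4, a matrix thrombospondin, rose by 1.53 (SE 0.33, adjusted p = 0.00602, 9 of 9). Pde6h fell by 1.12. Among the 26 tested bone matrix genes, 9 rose, 0 fell and 17 did not pass (11 and 0 adjusted over the list alone, mean 0.63, adjusted p = 2.34e-09, adjusted p = 0.137 with an estimated correlation). limma called 201 of 11412 genes, 144 higher and 57 lower (172 and 109 after quantile normalization), against 104 without vehicle replicate 4, and 16 with array weights. Of the day 85 osteoblast results calls ended with array weights (Col11a1, Cthrc1, Thbs4, Pde6h), without the arrays of outlying signal range (Cthrc1) and on leaving out 1 array (Col11a1 for vehicle replicate 3, Cthrc1 for vehicle replicate 4).

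On day 183 in osteoblasts Gng10, a G protein subunit, rose by 1.70 (SE 0.20, adjusted p = 5.27e-09, 10 of 10), Hipk1, a nuclear kinase, rose by 1.43 (SE 0.17, adjusted p = 4.97e-09, 10 of 10), and Eef1a1, a translation elongation factor, rose by 1.27 (SE 0.17, adjusted p = 9.53e-08, 10 of 10). Rasgrf1, a Ras activator, fell by 0.98 (SE 0.16, adjusted p = 3.52e-05, 10 of 10), with Semg1 and Snn lower as well (-0.90 and -0.84). Col1a1 had a value of 0.17 (SE 0.35, adjusted p = 0.862, 6 of 10). Of the 33 tested cell cycle genes 9 rose, 0 fell and 24 did not pass (13 and 0 adjusted over the list alone, mean 0.32, adjusted p = 4.93e-07, adjusted p = 0.358 with an estimated correlation). Among the 31 tested secretory pathway genes, 3 rose, 0 fell and 28 did not pass (7 and 0 adjusted over the list alone, mean 0.26, adjusted p = 0.000461, adjusted p = 0.461 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, rose by 0.68. Of the 11 tested granulocyte markers 3 rose, 0 fell and 8 did not pass (3 and 0 adjusted over the list alone, mean 0.27, adjusted p = 0.00308, adjusted p = 0.351 with an estimated correlation). In these arrays the marrow marker score was -0.10 in vehicle, 0.07 at 3 mg/kg and 0.16 at 50 mg/kg, and the signal range 2.68, 2.83 and 2.88. limma called 375 of 11412 genes, 259 higher and 116 lower (290 and 305 after quantile normalization), against 132 without vehicle replicate 2 and 671 without 50 mg/kg replicate 5, and 102 with the compared groups alone and 1148 with array weights. For the last dosing day in osteoblasts calls ended with the compared groups alone (Snn), with quantile normalization (secretory pathway genes, granulocyte markers) and on leaving out 1 array (Snn for 5 of 15).

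**Figure D2:**
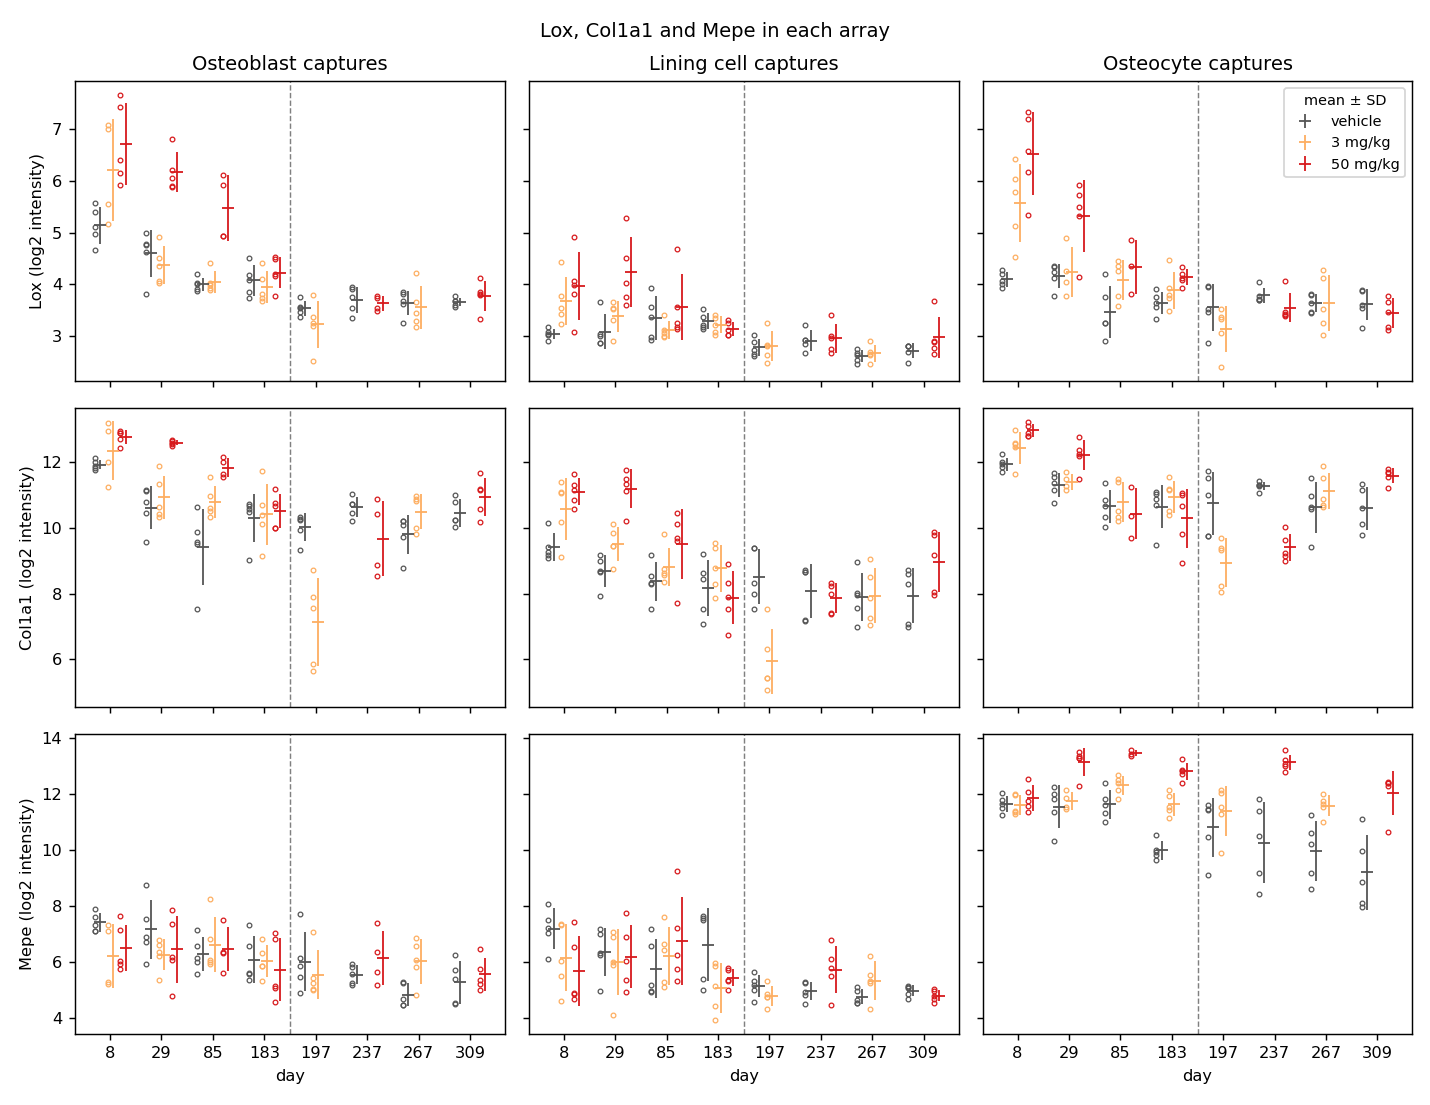
Log2 signal of Lox, Col1a1 and Mepe in each array (points) of the 3 captured cell types by day and treatment, with the mean and SD of each group. On day 8, 9 of 9 treated osteoblast arrays and 10 of 10 treated osteocyte arrays lay above the vehicle mean of Lox.

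In lining cells of day 8 Col11a1 rose by 1.70 (SE 0.32, adjusted p = 0.00302, 9 of 10), Car1 rose by 1.20 (SE 0.26, adjusted p = 0.0194, 10 of 10) and Omd rose by 0.92 (SE 0.19, adjusted p = 0.0132, 8 of 10). Slc22a3 fell by 1.21 (SE 0.24, adjusted p = 0.00775, 10 of 10). Ptgis, the prostacyclin synthase, fell by 1.17 (SE 0.25, adjusted p = 0.0135, 10 of 10). Of the 7 higher genes 6 were also higher in osteoblasts, where independent lists would share 0.179, and of the 29 lower ones 17 were also lower there, where independent lists would share 0.325. Among the 9 tested osteoclast regulators, 0 rose, 3 fell and 6 did not pass (0 and 3 adjusted over the list alone, mean -0.29, adjusted p = 0.00900, adjusted p = 0.137 with an estimated correlation, while the median was 0.00). limma called 36 of 11600 genes, 7 higher and 29 lower, against 4 without vehicle replicate 2 and 60 without 3 mg/kg replicate 4, and 2 with the compared groups alone and 207 with array weights. Among lining cell results of day 8 calls ended with the compared groups alone (Col11a1, Car1, Omd, Ptgis), with no filter (osteoclast regulators) and on leaving out 1 array (Car1 for 3 of 15, Omd for vehicle replicates 2 and 3, Slc22a3 for vehicle replicates 2 and 3, Ptgis for 3 of 15).

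With both doses averaged, few lining cell genes passed later. At 50 mg/kg alone 24, 114 and 116 did, against 72 on day 8. On day 29 Col11a1 rose by 1.67 (SE 0.32, adjusted p = 0.00626, 9 of 10), Sparc (osteonectin) rose by 1.44 (SE 0.30, adjusted p = 0.0173, 9 of 10), and Tnc (tenascin) fell by 0.93 (SE 0.19, adjusted p = 0.0139, 9 of 10). Of the 26 tested bone matrix genes 2 rose, 1 fell and 23 did not pass (8 and 1 adjusted over the list alone, mean 0.39, adjusted p = 1.14e-08, adjusted p = 0.0991 with an estimated correlation). limma called 5 of 11600 genes, 4 higher and 1 lower, against 2 without vehicle replicate 1 and 8 without vehicle replicate 5, and 2 with the compared groups alone and 10 with the signal range covariate. Day 29 calls ended with the compared groups alone (Col11a1, Sparc, Tnc), the mean of probe sets (Sparc) and array weights (Tnc). Leaving out 1 array ended Sparc (3 of 15) and Tnc (vehicle replicates 3 and 4).

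On day 85 Dnajc3, a chaperone, rose by 0.94 (SE 0.20, adjusted p = 0.0167, 10 of 10). Gimap7 fell by 0.96 (SE 0.20, adjusted p = 0.0167, 10 of 10). Among the 9 tested megakaryocyte markers, 0 rose, 0 fell and 9 did not pass (0 and 0 adjusted over the list alone, mean 0.29, adjusted p = 0.00997, adjusted p = 0.557 with an estimated correlation). limma called 9 of 11600 genes, 5 higher and 4 lower (10 and 26 after quantile normalization), against 1 without vehicle replicate 3 and 17 without vehicle replicate 2, and 0 with array weights and 52 with the signal range covariate. Among lining cell results of day 85 calls ended with array weights (Dnajc3, Gimap7), with the compared groups alone (Dnajc3, Gimap7) and on leaving out 1 array (Dnajc3 for vehicle replicates 1 and 3, Gimap7 for 3 of 15, megakaryocyte markers for vehicle replicate 1 and 3 mg/kg replicate 5).

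On day 183 Srsf2, a splicing factor, rose by 0.66 (SE 0.11, adjusted p = 0.00155, 10 of 10), Hipk1 rose by 0.88 (SE 0.18, adjusted p = 0.0204, 10 of 10), Anxa1, a phospholipid-binding protein, rose by 0.72 (SE 0.15, adjusted p = 0.0204, 10 of 10), and Mgmt, a DNA repair enzyme, fell by 0.69 (SE 0.16, adjusted p = 0.0469, 10 of 10) in lining cells. All 5 genes higher there were also higher in osteoblasts, where independent lists would share 0.115. Of the 11 tested erythroid markers 0 rose, 0 fell and 11 did not pass (2 and 0 adjusted over the list alone, mean 0.36, adjusted p = 4.68e-06, adjusted p = 0.206 with an estimated correlation). limma called 6 of 11600 genes, 5 higher and 1 lower (14 and 18 after quantile normalization), against 0 without vehicle replicate 4 and 12 without vehicle replicate 3, and 242 with array weights. Day 183 calls ended with the mean of probe sets (Srsf2). Leaving out 1 array ended Srsf2 (vehicle replicate 4), Hipk1 and Anxa1 (3 of 15 each) and Mgmt (10 of 15).

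In osteocytes of day 8 Lox rose by 1.95 (SE 0.23, adjusted p = 1.27e-08, 10 of 10), and Omd rose by 1.58 (SE 0.28, adjusted p = 0.000559, 10 of 10). Slc13a5, a citrate transporter, rose by 1.47 (SE 0.24, adjusted p = 0.000185, 10 of 10). Col11a1 rose by 1.50 (SE 0.34, adjusted p = 0.0192, 9 of 10), while Cxcl14, a chemokine, fell by 1.12 (SE 0.23, adjusted p = 0.00700, 9 of 10) and Cfap100 fell by 0.97 (SE 0.18, adjusted p = 0.00122, 10 of 10). The 4 higher genes shared with osteoblasts were Ablim3, Lox, Omd and Slc13a5, where independent lists would share 0.359. Among the 23 tested collagen synthesis enzymes, 2 rose, 0 fell and 21 did not pass (7 and 0 adjusted over the list alone, mean 0.35, adjusted p = 6.2e-10, adjusted p = 0.0736 with an estimated correlation). Of the 12 tested osteoclast markers 0 rose, 0 fell and 12 did not pass (0 and 4 adjusted over the list alone, mean -0.25, adjusted p = 0.000384, adjusted p = 0.0524 with an estimated correlation). limma called 34 of 11859 genes, 14 higher and 20 lower (22 and 17 after quantile normalization), against 8 without vehicle replicate 3, and 352 with array weights. Among osteocyte results of day 8 calls ended with the mean of probe sets (Col11a1) and on leaving out 1 array (Col11a1 for 3 of 15, Cxcl14 for vehicle replicate 3).

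In osteocytes of day 29 Magi1, a junction scaffold protein, rose by 1.98 (SE 0.35, adjusted p = 0.000785, 9 of 9), and Ackr3, a scavenging receptor of the chemokine Cxcl12, rose by 1.381 (SE 0.34, adjusted p = 0.0474, 7 of 9). Sema6d, a guidance cue, rose by 1.35 (SE 0.26, adjusted p = 0.00298, 8 of 9). Gzmb, a granzyme of lymphocytes, rose by 1.31, and Slfn2, a T-cell regulator, fell by 0.61. Among the 22 tested TGF-beta and BMP genes, 3 rose, 0 fell and 19 did not pass (6 and 0 adjusted over the list alone, mean 0.35, adjusted p = 8.21e-07, adjusted p = 0.0524 with an estimated correlation). Examples were Tgfb3 (1.10) and Ltbp1 (0.83). The marrow marker score was -0.80 in vehicle and -1.23 at 50 mg/kg. limma called 25 of 11859 genes, 24 higher and 1 lower (48 and 13 after quantile normalization), against 13 without vehicle replicate 1 and 45 without 50 mg/kg replicate 1, and 201 with array weights. Among osteocyte results of day 29 calls ended with no filter (Ackr3), with the compared groups alone (Tgfb3, Gzmb) and on leaving out 1 array (Ackr3 for 9 of 14, Gzmb for 9 of 14, Slfn2 for vehicle replicate 1).

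On day 85 in osteocytes Tnnc1, a troponin, rose by 2.16 (SE 0.35, adjusted p = 1.91e-05, 7 of 8), and Wnt5b, a Wnt ligand, rose by 1.75 (SE 0.26, adjusted p = 3.05e-06, 8 of 8). Magi1 rose by 1.74 (SE 0.36, adjusted p = 0.000725, 7 of 8), with Dclk1 (1.69) beside them. Vpreb3, a gene of B-cell precursors, fell by 1.52 (SE 0.31, adjusted p = 0.000763, 8 of 8). Tifa, an adaptor of NF-kappaB signalling, fell by 1.44 (SE 0.26, adjusted p = 0.000122, 7 of 8). Of the 21 tested immediate early and heat shock genes 5 rose, 1 fell and 15 did not pass (8 and 1 adjusted over the list alone, mean 0.33, adjusted p = 0.00229, adjusted p = 0.137 with an estimated correlation). Among the 15 tested endothelial markers, 4 rose, 0 fell and 11 did not pass (5 and 0 adjusted over the list alone, mean 0.28, adjusted p = 0.0284, adjusted p = 0.391 with an estimated correlation). Examples were Emcn (1.17) and Plvap (1.05). Of the 8 tested B-lineage markers 0 rose, 2 fell and 6 did not pass (0 and 2 adjusted over the list alone, mean -0.37, adjusted p = 0.0125, adjusted p = 0.351 with an estimated correlation). Those lower were Ms4a1 (-1.20) and Blnk (-0.72). The marrow marker score was -1.08 in vehicle and -1.43 at 50 mg/kg. limma called 747 of 11859 genes, 525 higher and 222 lower (604 and 471 after quantile normalization), against 41 with the compared groups alone. It was 67 with array weights. Among osteocyte results of day 85 calls ended with array weights (Magi1, Vpreb3, Emcn, Plvap, Ms4a1, Blnk), with the compared groups alone (Magi1, Vpreb3, Tifa, Plvap, Ms4a1, Blnk), with the mean of probe sets (endothelial markers) and on leaving out 1 array (Ms4a1 for 50 mg/kg replicate 3, Blnk for 3 of 13, endothelial markers for 3 of 13).

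On day 183 in osteocytes Mepe rose by 2.24 (SE 0.37, adjusted p = 5.02e-05, 10 of 10), Bambi, a decoy receptor that blocks TGF-beta signals, rose by 2.14 (SE 0.37, adjusted p = 8.94e-05, 10 of 10), Mef2c, a transcription factor of the sclerostin gene, rose by 2.05 (SE 0.30, adjusted p = 1.51e-06, 10 of 10), and Ackr3 rose by 1.89 (SE 0.33, adjusted p = 0.000109, 10 of 10). Mepe changed by 1.65 at 3 mg/kg and 2.82 at 50 mg/kg. Fcnb, a ficolin of myeloid cells, fell by 0.99 (SE 0.24, adjusted p = 0.00822, 10 of 10), and the immunoglobulin gene Ighvl1 fell by 1.28. Sost, which encodes sclerostin, had 0.18 (SE 0.12, adjusted p = 0.599, 7 of 10). Among the 20 tested osteocyte markers, 6 rose, 0 fell and 14 did not pass (7 and 0 adjusted over the list alone, mean 0.41, adjusted p = 0.000127, adjusted p = 0.183 with an estimated correlation). Examples were Pdpn (1.59), Dmp1 (1.59) and Fam20c (1.002). Of the 18 tested Wnt target genes 4 rose, 0 fell and 14 did not pass (5 and 0 adjusted over the list alone, mean 0.19, adjusted p = 0.0466, adjusted p = 0.351 with an estimated correlation). Ccn4, Cd44 and Gja1, a gap junction protein, rose by 1.20, 0.88 and 0.61. The marrow marker score was -0.98 in vehicle and -1.20 at 50 mg/kg. Higher genes shared with day 85 numbered 89, where independent lists would share 9.21. limma called 244 of 11859 genes, 208 higher and 36 lower (258 and 124 after quantile normalization), against 99 without vehicle replicate 3, and 691 with array weights. Among osteocyte results of day 183 calls ended with quantile normalization (Gja1, Wnt target genes), with the mean of probe sets (Gja1, Wnt target genes), with no filter (Wnt target genes) and on leaving out 1 array (Gja1 for vehicle replicate 2, Wnt target genes for 8 of 15).

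**Figure D3:**
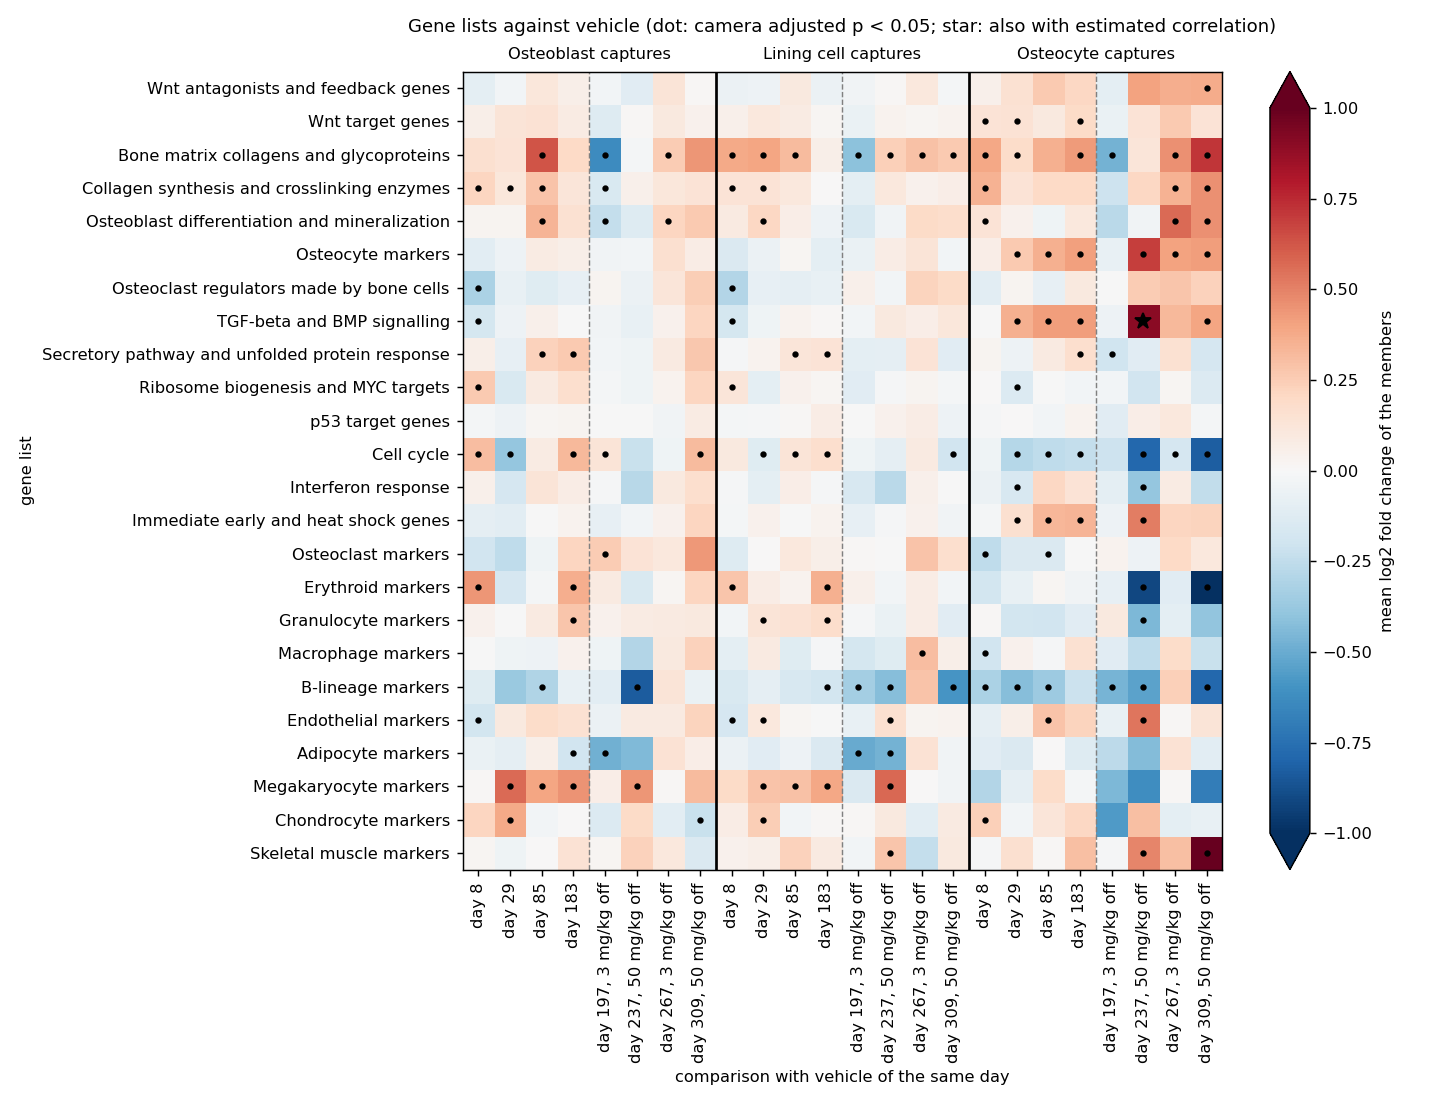
Mean log2 fold change of each gene list (rows) in each comparison with vehicle (columns), with a dot where camera's adjusted p was under 0.05 and a star where it also was with an estimated correlation. The star marks the TGF-beta and BMP list in osteocytes on day 237 after 50 mg/kg.

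The plot of gene lists holds 79 calls in 288 tests during dosing, of which 0 held with an estimated correlation, and 54 calls in 288 tests after withdrawal, of which 1 held. The p53 target genes were not called in any of these comparisons, with adjusted p from 0.317 in osteoblasts after 3 mg/kg on day 267 to 0.992 in lining cells on day 85.

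The doses were compared as 50 minus 3 mg/kg averaged over the dosing days. Arrays counted are those of 50 mg/kg beyond the 3 mg/kg mean of the day. In osteoblasts Col11a1 was higher at 50 mg/kg by 1.25 (SE 0.22, adjusted p = 0.000134, 18 of 19), Slc13a5 by 1.09 (SE 0.13, adjusted p = 2.42e-09, 18 of 19), and Serpinf1, a collagen-binding inhibitor of angiogenesis, by 1.05 (SE 0.22, adjusted p = 0.00141, 17 of 19). Ctsk and Acp5 were lower, with differences of -1.28 (SE 0.15, adjusted p = 2.42e-09, 19 of 19) and -1.04 (SE 0.14, adjusted p = 4.2e-07, 19 of 19). limma called 289 of 11412 genes, 160 higher and 129 lower, against 457 with the signal range covariate.

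In lining cells Col11a1 again differed by 1.09 (SE 0.18, adjusted p = 0.000206, 17 of 20) and Omd by 0.66 (SE 0.11, adjusted p = 0.000206, 15 of 20), while Spp1, or osteopontin, differed by -0.998 (SE 0.20, adjusted p = 0.00181, 16 of 20). limma called 75 of 11600 genes, 40 higher and 35 lower, against 48 without day 85 50 mg/kg replicate 5 and 115 without day 29 3 mg/kg replicate 4, and 24 with the compared groups alone and 211 with the signal range covariate.

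In osteocytes Mgp, an inhibitor of mineralization, was higher by 1.94 (SE 0.47, adjusted p = 0.00151, 15 of 18), Pdpn, a protein of young osteocytes, by 1.70 (SE 0.21, adjusted p = 1.84e-09, 18 of 18), and Sparcl1, a matrix glycoprotein, by 1.61 (SE 0.17, adjusted p = 3.36e-12, 15 of 18). Ighvl1 differed by -1.13 (SE 0.14, adjusted p = 8.53e-10, 18 of 18) and Tifa by -1.06 (SE 0.15, adjusted p = 1.04e-07, 17 of 18). limma called 1774 of 11859 genes, 811 higher and 963 lower.

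Against vehicle, limma called 0 (791), 8, 10 and 69 genes in osteoblasts at 3 mg/kg on days 8, 29, 85 and 183. At 50 mg/kg it called 935, 3241, 510 and 505. Brackets hold counts at an unadjusted p under 0.05. Lining cells had 0 (660), 0 (731), 4 and 0 (520) genes at 3 mg/kg, and 72, 24, 114 and 116 at 50 mg/kg. The osteocyte numbers were 1, 0 (429), 173 and 0 (549) at 3 mg/kg, and 110, 771, 1203 and 757 at 50 mg/kg.

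Subtracting the day 8 response from that of day 183 tested whether the response changed with the length of dosing, and the arrays counted are those of day 183 beyond the mean response of day 8. In osteoblasts the responses of Lox and Mybl2, a cell cycle transcription factor, differed by -1.30 (SE 0.31, adjusted p = 0.0253, 10 of 10) and by -0.89 (SE 0.21, adjusted p = 0.0238, 10 of 10), while that of Gng10 differed by 1.384 (SE 0.29, adjusted p = 0.0097, 10 of 10). Arsb, a lysosomal sulfatase, differed by 1.51 (SE 0.37, adjusted p = 0.0264, 10 of 10). limma called 64 of 11412 genes, 51 higher and 13 lower (104 and 116 after quantile normalization), against 12 without day 183 vehicle replicate 2 and 211 without day 8 vehicle replicate 2, and 24 with the compared groups alone and 425 with array weights. For the osteoblast time contrast calls ended with the mean of probe sets (Lox, Mybl2, Arsb), with the compared groups alone (Lox, Mybl2) and on leaving out 1 array (Lox for 3 of 29, Mybl2 for 4 of 29, Arsb for 6 of 29).

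In lining cells the 2 genes called were Srsf2, higher by 0.84 (SE 0.16, adjusted p = 0.0165, 10 of 10), and Son, another splicing factor, higher by 0.80 (SE 0.17, adjusted p = 0.0343, 10 of 10). limma called 2 of 11600 genes, 2 higher and 0 lower, against 0 without day 8 vehicle replicate 1 and 4 without day 8 vehicle replicate 5, and 0 with the compared groups alone and 74 with array weights. For the lining cell time contrast calls ended with the mean of probe sets (Srsf2, Son), with the compared groups alone (Srsf2, Son), with quantile normalization (Son) and on leaving out 1 array (Srsf2 for 5 of 30, Son for 14 of 30).

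In osteocytes the Mepe response of day 183 exceeded that of day 8 by 2.14 (SE 0.53, adjusted p = 0.0323, 10 of 10) and that of Mef2c by 1.77 (SE 0.42, adjusted p = 0.0245, 10 of 10), while Lox differed by -1.58 (SE 0.33, adjusted p = 0.00984, 10 of 10) and Slc13a5 by -1.44 (SE 0.34, adjusted p = 0.0245, 10 of 10). Mepe had means of 11.64 in vehicle, 11.61 at 3 mg/kg and 11.87 at 50 mg/kg on day 8, and of 9.99, 11.64 and 12.82 on day 183, days whose array titles fall in different number blocks. limma called 61 of 11859 genes, 49 higher and 12 lower (49 and 31 after quantile normalization), against 9 without day 183 vehicle replicate 3, and 621 with array weights. For the osteocyte time contrast calls ended with the signal range covariate (Mepe, Mef2c), with the mean of probe sets (Mef2c) and on leaving out 1 array (Mepe for 8 of 30, Mef2c for 5 of 30, Slc13a5 for 4 of 30).

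Differences in response between cell types were tested directly, with the response averaged over the dosing days and the arrays counted being those of the first-named cell type beyond the mean response of the other. For osteoblasts minus osteocytes the Mepe response differed by -1.58 (SE 0.31, adjusted p = 0.000222, 36 of 38) and that of Magi1 by -1.54 (SE 0.19, adjusted p = 7.35e-11, 37 of 38). Srm, the spermidine synthase, differed by 0.88 (SE 0.18, adjusted p = 0.000567, 36 of 38) and Igfbp5 by 0.77 (SE 0.21, adjusted p = 0.0162, 30 of 38). limma called 446 of 12507 genes, 156 higher and 290 lower, against 710 with the signal range covariate. For osteoblasts against osteocytes calls ended with the mean of probe sets (Igfbp5).

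For lining cells minus osteocytes the Mepe response differed by -1.67 (SE 0.31, adjusted p = 6.03e-05, 33 of 40) and that of Magi1 by -1.49 (SE 0.19, adjusted p = 3.83e-10, 39 of 40). Slc4a1, the anion exchanger of red cells, differed by 0.67 (SE 0.16, adjusted p = 0.00533, 39 of 40). limma called 334 of 12507 genes, 68 higher and 266 lower, against 518 with quantile normalization. Between osteoblasts and lining cells limma called 0 of 12507 genes (670 at an unadjusted p under 0.05). With array weights it called 1 gene, and without the lining cell day 29 3 mg/kg replicate 3 also 1.

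After dosing stopped, comparisons with vehicle asked which differences were present in the treatment-free period. On day 197, after 3 mg/kg, Col1a1 fell by 2.90 (SE 0.41, adjusted p = 2.99e-06, 5 of 5) in osteoblasts, fell by 2.57 (SE 0.45, adjusted p = 0.00168, 5 of 5) in lining cells and fell by 1.80 (SE 0.35, adjusted p = 0.00171, 5 of 5) in osteocytes. Bglap, which encodes osteocalcin, fell by 2.51 (SE 0.38, adjusted p = 1.17e-05, 5 of 5) in osteoblasts and fell by 2.11 (SE 0.45, adjusted p = 0.027, 5 of 5) in lining cells, and Col1a2 changed by -2.48 and -2.33 there. The lower genes of osteoblasts and lining cells shared 3 members, those of osteoblasts and osteocytes 4 and those of lining cells and osteocytes 4, where independent lists would share 0.00498, 0.0925 and 0.08. Among the 26 tested bone matrix genes, 0 rose, 4 fell and 22 did not pass (0 and 9 adjusted over the list alone, mean -0.63, adjusted p = 6.63e-16, adjusted p = 0.0562 with an estimated correlation). limma called 9 of 11412 genes, 1 higher and 8 lower, against 5 without 3 mg/kg replicate 3 and 14 without 3 mg/kg replicate 5, and 24 with array weights.

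The signal range of osteocytes of day 197 was 3.35 in vehicle and 3.13 after 3 mg/kg. In lining cells of that day limma called 7 of 11600 genes, 0 higher and 7 lower, against 1 without 3 mg/kg replicate 4, and 2 with the compared groups alone and 20 with array weights. After 3 mg/kg, in lining cells of day 197 calls ended with the compared groups alone (Col1a1, Bglap), with quantile normalization (Bglap), with the mean of probe sets (Bglap), with the signal range covariate (Bglap) and on leaving out 1 array (Bglap for 6 of 10, Col1a2 for 3 mg/kg replicate 4). In osteocytes of that day limma called 132 of 11859 genes, 2 higher and 130 lower, against 45 without 3 mg/kg replicate 2, and 1107 with array weights. Quantile normalization left 2 higher and 40 lower, and the signal range as covariate 1 and 20.

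In osteocytes of day 267 after 3 mg/kg Ackr3 rose by 1.92 (SE 0.38, adjusted p = 0.000941, 5 of 5), Slit2, a secreted guidance cue, rose by 1.84 (SE 0.40, adjusted p = 0.00238, 5 of 5), and Bambi rose by 1.83 (SE 0.43, adjusted p = 0.00625, 5 of 5), while Cdc34, a ubiquitin-conjugating enzyme, fell by 0.82 (SE 0.20, adjusted p = 0.00969, 5 of 5). Of the 24 tested osteoblast differentiation genes 7 rose, 0 fell and 17 did not pass (13 and 0 adjusted over the list alone, mean 0.57, adjusted p = 1.54e-06, adjusted p = 0.295 with an estimated correlation). Among them were Cdh11 (1.68), Pth1r (1.29) and Dlx5 (1.26). The signal range was 3.20 in vehicle and 3.39 after 3 mg/kg. limma called 431 of 11859 genes, 410 higher and 21 lower, against 151 without vehicle replicate 5, and 1334 with array weights. Quantile normalization left 107 higher and 11 lower, and the signal range as covariate 118 and 13. After 3 mg/kg, in osteocytes of day 267 calls ended with the signal range covariate (Bambi, Cdc34, Dlx5), with quantile normalization (Cdc34), with the mean of probe sets (Cdc34) and on leaving out 1 array (Cdc34 for vehicle replicate 5).

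In lining cells of day 267 Rpa3, a DNA replication protein, rose by 1.44 (SE 0.23, adjusted p = 0.000163, 5 of 5), and Cd48, a leukocyte surface protein, rose by 1.36 (SE 0.29, adjusted p = 0.00555, 5 of 5). Fat1, a cadherin, rose by 1.29 (SE 0.34, adjusted p = 0.0391, 5 of 5). Clcn2, a chloride channel, fell by 0.85 (SE 0.20, adjusted p = 0.0145, 5 of 5). Among the 14 tested macrophage markers, 0 rose, 0 fell and 14 did not pass (4 and 0 adjusted over the list alone, mean 0.31, adjusted p = 0.00689, adjusted p = 0.486 with an estimated correlation). The signal range was 3.27 in vehicle and 3.44 after 3 mg/kg. limma called 125 of 11600 genes, 118 higher and 7 lower, against 9 without vehicle replicate 1 and 191 without vehicle replicate 3, and 746 with array weights. Quantile normalization left 25 higher and 3 lower, and the signal range as covariate 30 and 7. After 3 mg/kg, in lining cells of day 267 calls ended with quantile normalization (Fat1, Clcn2), with the signal range covariate (Fat1) and on leaving out 1 array (Cd48 for vehicle replicate 1, Fat1 for 7 of 10, Clcn2 for vehicle replicate 1 and 3 mg/kg replicate 5). In osteoblasts of day 267 limma called 0 of 11412 genes (388 at an unadjusted p under 0.05).

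In osteocytes of day 237 after 50 mg/kg Bambi rose by 3.22 (SE 0.43, adjusted p = 1.63e-08, 5 of 5), Magi1 rose by 3.17 (SE 0.39, adjusted p = 2.08e-09, 5 of 5) and Ackr3 rose by 3.11 (SE 0.38, adjusted p = 1.66e-09, 5 of 5). Bglap fell by 2.11 (SE 0.31, adjusted p = 3.07e-07, 5 of 5), and Car3, a carbonic anhydrase of fat and muscle, fell by 2.10 (SE 0.42, adjusted p = 0.000163, 5 of 5). Fcna, a ficolin of macrophages, fell by 2.02 (SE 0.29, adjusted p = 1.12e-07, 5 of 5). Sost rose by 0.58 (SE 0.14, adjusted p = 0.00183, 5 of 5). Of the 22 tested TGF-beta and BMP genes 12 rose, 0 fell and 10 did not pass (13 and 0 adjusted over the list alone, mean 0.90, adjusted p = 3.89e-12, adjusted p = 0.00313 with an estimated correlation). Examples were Id1 (2.93), Tgfb2 (2.62), Ccn2 (2.33) and Ltbp3 (1.63). Among the 20 tested osteocyte markers, 9 rose, 0 fell and 11 did not pass (9 and 0 adjusted over the list alone, mean 0.69, adjusted p = 3.48e-07, adjusted p = 0.0562 with an estimated correlation). Examples there were Mepe (2.86), Pdpn (2.20), Fam20c (1.75) and Dmp1 (1.69). Of the 33 tested cell cycle genes 0 rose, 24 fell and 9 did not pass (0 and 31 adjusted over the list alone, mean -0.78, adjusted p = 6.63e-16, adjusted p = 0.295 with an estimated correlation). Among the 15 tested endothelial markers, 7 rose, 0 fell and 8 did not pass (8 and 0 adjusted over the list alone, mean 0.54, adjusted p = 1.74e-05, adjusted p = 0.0792 with an estimated correlation). Of the 20 tested interferon response genes 0 rose, 3 fell and 17 did not pass (0 and 4 adjusted over the list alone, mean -0.39, adjusted p = 0.00468, adjusted p = 0.421 with an estimated correlation). The marrow marker score was -0.26 in vehicle and -0.90 after 50 mg/kg. Of the higher genes 164 were also higher on day 183, where independent lists would share 14.6. limma called 1566 of 11859 genes, 835 higher and 731 lower, against 783 with the compared groups alone.

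In osteocytes of day 309 after 50 mg/kg Mepe rose by 2.83 (SE 0.43, adjusted p = 1.5e-06, 5 of 5), and Tpm2, a tropomyosin, rose by 2.29 (SE 0.34, adjusted p = 8.99e-07, 5 of 5). Tnnc2, a muscle troponin, rose by 2.46 (SE 0.75, adjusted p = 0.0153, 5 of 5). Jchain, the joining chain of immunoglobulins, fell by 2.46 (SE 0.32, adjusted p = 4.00e-08, 5 of 5), and Stfa2l2, a stefin of myeloid cells, fell by 2.87 (SE 0.52, adjusted p = 4.48e-05, 5 of 5). Hipk1 fell by 2.34 (SE 0.25, adjusted p = 5.67e-11, 5 of 5). Among the 27 tested bone matrix genes, 12 rose, 0 fell and 15 did not pass (15 and 0 adjusted over the list alone, mean 0.72, adjusted p = 1.47e-08, adjusted p = 0.248 with an estimated correlation). Examples were Col6a1 (1.80), Tnc (1.57) and Col3a1 (1.50). Of the 14 tested skeletal muscle markers 9 rose, 0 fell and 5 did not pass (10 and 0 adjusted over the list alone, mean 0.99, adjusted p = 6.14e-07, adjusted p = 0.307 with an estimated correlation). Among the 11 tested Wnt antagonist and feedback genes, 3 rose, 0 fell and 8 did not pass (3 and 0 adjusted over the list alone, mean 0.37, adjusted p = 0.0327, adjusted p = 0.274 with an estimated correlation). Of the 33 tested cell cycle genes 0 rose, 25 fell and 8 did not pass (0 and 28 adjusted over the list alone, mean -0.82, adjusted p = 4.75e-15, adjusted p = 0.295 with an estimated correlation). The marrow marker score was -0.04 in vehicle and -0.79 after 50 mg/kg. With day 237, 177 higher and 319 lower genes were shared, where independent lists would share 44.8 and 80.4. limma called 1941 of 11859 genes, 636 higher and 1305 lower (813 and 933 after quantile normalization), against 1126 without 50 mg/kg replicate 5, and 1000 with the compared groups alone. After 50 mg/kg, in osteocytes of day 309 calls ended with the signal range covariate (Tnnc2), with no filter (Wnt antagonist and feedback genes), with quantile normalization (Wnt antagonist and feedback genes), with the mean of probe sets (Wnt antagonist and feedback genes) and on leaving out 1 array (Tnnc2 for 50 mg/kg replicate 2, Wnt antagonist and feedback genes for 3 of 10). Tnnc2 was 1.58 without 50 mg/kg replicate 2.

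In osteoblasts of day 237 after 50 mg/kg Pck1, an enzyme of gluconeogenesis, fell by 1.92 (SE 0.48, adjusted p = 0.00535, 4 of 4), and Gstt3, a glutathione transferase, fell by 1.91 (SE 0.46, adjusted p = 0.00422, 4 of 4). Stfa3 fell by 1.93 (SE 0.58, adjusted p = 0.0216, 4 of 4). Lrrfip1, a nucleic acid sensor, rose by 1.87 (SE 0.35, adjusted p = 0.000407, 4 of 4), and Golim4, a Golgi membrane protein, rose by 1.61 (SE 0.31, adjusted p = 0.000528, 4 of 4). Mgp rose by 1.52 (SE 0.44, adjusted p = 0.0176, 4 of 4). Among the 8 tested B-lineage markers, 0 rose, 4 fell and 4 did not pass (0 and 5 adjusted over the list alone, mean -0.83, adjusted p = 4.78e-05, adjusted p = 0.261 with an estimated correlation). Their members Jchain (-1.45), Pou2af1 (-1.30), Blnk (-1.12) and Ms4a1 (-1.08) fell. The signal range was 3.44 in vehicle and 3.22 after 50 mg/kg, and the marrow marker score 0.86 and 0.61. limma called 1222 of 11412 genes, 343 higher and 879 lower (379 and 605 after quantile normalization), against 686 without vehicle replicate 4, and 463 with the signal range covariate and 1887 with array weights. After 50 mg/kg, in osteoblasts of day 237 calls ended with the signal range covariate (Stfa3), with the mean of probe sets (Lrrfip1, Golim4) and on leaving out 1 array (Stfa3 for 4 of 9, Mgp for vehicle replicate 2 and 50 mg/kg replicate 4). Mgp was 0.81 without 50 mg/kg replicate 4.

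In lining cells of day 237 after 50 mg/kg Pck1 fell by 1.66 (SE 0.43, adjusted p = 0.0247, 5 of 5), Car3 fell by 1.88 (SE 0.47, adjusted p = 0.0209, 5 of 5) and Stfa2l2 fell by 1.93 (SE 0.44, adjusted p = 0.012, 5 of 5). Selp, the P-selectin of platelets and endothelium, rose by 1.24 (SE 0.23, adjusted p = 0.00126, 5 of 5). Myl9, a myosin light chain, rose by 1.14 (SE 0.25, adjusted p = 0.00861, 5 of 5). Of the 15 tested adipocyte markers 0 rose, 5 fell and 10 did not pass (0 and 7 adjusted over the list alone, mean -0.48, adjusted p = 0.00466, adjusted p = 0.342 with an estimated correlation). Examples were Adipoq (-1.61), Plin1 (-1.43) and Cidec (-1.10). With osteoblasts 48 lower genes were shared, where independent lists would share 8.34. limma called 168 of 11600 genes, 61 higher and 107 lower (72 and 69 after quantile normalization), against 59 without vehicle replicate 4 and 255 without vehicle replicate 5, and 724 with array weights. After 50 mg/kg, in lining cells of day 237 calls ended with the mean of probe sets (Plin1), with array weights (adipocyte markers) and on leaving out 1 array (Pck1 for 4 of 10, Car3 for 3 of 10, Stfa2l2 for vehicle replicate 4, Adipoq for 50 mg/kg replicate 2, Plin1 for 3 of 10, Cidec for vehicle replicate 4, adipocyte markers for vehicle replicate 5).

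Day 309 osteoblasts had more genes higher than lower after 50 mg/kg. Cd48 rose by 1.61 (SE 0.31, adjusted p = 0.00103, 5 of 5), and Rbm3, a cold-induced RNA-binding protein, rose by 1.51 (SE 0.32, adjusted p = 0.0019, 5 of 5). Cpox, an enzyme of heme synthesis, rose by 1.45 (SE 0.27, adjusted p = 0.000765, 5 of 5). Bcl6b, a transcriptional repressor, fell by 1.57 (SE 0.33, adjusted p = 0.0019, 5 of 5). Among the 33 tested cell cycle genes, 6 rose, 0 fell and 27 did not pass (11 and 0 adjusted over the list alone, mean 0.31, adjusted p = 0.00873, adjusted p = 0.707 with an estimated correlation). The median of all genes was 0.10, and 0.00 after quantile normalization, and the signal range was 3.08 in vehicle and 3.41 after 50 mg/kg. limma called 1203 of 11412 genes, 985 higher and 218 lower (311 and 263 after quantile normalization), against 144 without vehicle replicate 3 and 1833 without vehicle replicate 1. With the signal range as covariate it was 0. After 50 mg/kg, in osteoblasts of day 309 calls ended with the signal range covariate (Cd48, Rbm3, Cpox, Bcl6b), with the compared groups alone (Cd48, Rbm3), with quantile normalization (cell cycle genes) and on leaving out 1 array (cell cycle genes for vehicle replicate 3).

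In lining cells of day 309 Jchain fell by 2.30 (SE 0.29, adjusted p = 5.98e-08, 5 of 5), Stfa2l2 fell by 1.996 (SE 0.44, adjusted p = 0.00986, 5 of 5) and Bcl6b fell by 1.70 (SE 0.31, adjusted p = 0.00119, 5 of 5). Cxcr5, a chemokine receptor of B cells, rose by 0.84 (SE 0.20, adjusted p = 0.0232, 5 of 5). Of the lower genes 35 were also lower in osteocytes, where independent lists would share 4.34. limma called 47 of 11600 genes, 9 higher and 38 lower, against 11 without 50 mg/kg replicate 4 and 133 without 50 mg/kg replicate 2, and 0 with the compared groups alone and 296 with array weights. After 50 mg/kg, in lining cells of day 309 calls ended with the compared groups alone (Jchain, Stfa2l2, Bcl6b, Cxcr5), with the mean of probe sets (Bcl6b, Cxcr5) and on leaving out 1 array (Stfa2l2 for 50 mg/kg replicates 4 and 5, Cxcr5 for 5 of 10).

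Of the genes fixed for reporting whatever their p, Dkk1, Runx2 and Sp7 had no probe set listed with them in the table used here, and 20 of 204 tests during dosing and 35 of 204 after it passed. After 50 mg/kg Cdkn1a rose on day 237 in osteocytes (1.42), and Ibsp and Acp5 rose there on day 309 (0.80 and 0.99).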

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

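The tests with the signal range and the comparison of collagen with osteoblast differentiation genes were chosen after results were seen. An array stood apart from its group in signal range in 3 of 59 groups, and chance sets about 1 in 20 groups apart (2.95 groups): lining cells at 50 mg/kg on day 8, replicate 3 (2.61, mean of the others 3.11), osteoblasts of vehicle on day 85, replicate 4 (2.95, others 3.07), and osteocytes at 3 mg/kg on day 29, replicate 2 (2.66, others 3.04). Tests of the difference itself set the responses of days 183 and 8 apart for 64 genes in osteoblasts, 2 in lining cells and 61 in osteocytes. The response also differed between cell types, for 446 genes between osteoblasts and osteocytes and 334 between lining cells and osteocytes.

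In osteocyte captures 50 mg/kg was followed on day 237 by higher values of a part of the osteocyte markers and TGF-beta genes, with a median of 1.29 (median SE 0.25) over the 21 called genes of both lists. With the marrow marker score as covariate the median was 1.01 (median SE 0.27) and 14 of the 21 genes passed. Its slope rests on variation within groups, so it cannot decide on fewer marrow cells. The array signal range (3.08 in vehicle, 3.04 after 50 mg/kg) as covariate left 1.33 (median SE 0.24) and all 21 genes. That argues against it as the whole cause. A change of osteocytes after dosing and a larger share of them, which was not tested, stay open as hypotheses.

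Osteoblasts of day 29 had 1411 genes lower than vehicle, with a median of -0.57 (median SE 0.16). With the array signal range as covariate the median was -0.31 (median SE 0.15) and 87 of the genes passed, and with the marrow marker score, for fewer marrow cells, it was -0.44 (median SE 0.16) and 477 passed. Calls ended because the fold changes shrank, while the standard errors did not widen. The signal range, the share of marrow cells and the antibody itself cannot be told apart here, since the signal range moved with dose. The bound first written, a median plus its SE nearer to 0 than the midpoint between 0 and the median without covariate, is met by both values, but that midpoint lies within 1 SE of each, and so they do not decide.

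Several collagen genes were lower than vehicle in all 3 cell types on day 197 after 3 mg/kg, with a median of -1.75 (median SE 0.38) over 10 called values, 3 in osteoblasts, 2 in lining cells and 5 in osteocytes. The array signal range as covariate left -1.73 (median SE 0.37, 8 of 10 passed). Vehicle of day 197 differed from other vehicle days in these genes by a median of 0.17 (median SE 0.29). These values argue against the signal range and high vehicle arrays as the whole cause over these genes together. Osteoblast differentiation genes had a median of -0.11 (68 values, median SE 0.24). Normalized vehicle osteoblasts and lining cells hardly differed in them (median 0.08), so they cannot test for fewer bone-forming cells. Array titles fall in 3 number blocks, and against the vehicle days of its own block alone (237, 267 and 309), chosen after seeing the data, vehicle of day 197 differed by 0.51 (median SE 0.31, midpoint of the fall 0.88), with 7 of 10 treated values called lower. High vehicle arrays stay open for Col5a2 in osteoblasts (adjusted p = 0.066) and for Col11a2 and Col5a2 in osteocytes (0.102 and 0.201). Lower collagen expression and fewer bone-forming cells stay open as hypotheses, as does the signal range in lining cells and osteocytes.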

How the results depend on the processing

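Covariate fits on the signal range, fits without arrays of outlying signal range, and the leaving out of arrays in the vehicle pairs, the response and the gene lists were chosen after seeing the data, as were the compared groups and the mean of probe sets for gene lists. Of 352 called values of named and fixed genes 225 kept their direction and side of the threshold in every setting but the block below, 244 without each array and 204 in both. Of 163 list calls 119 held in the settings other than the estimated correlation, 112 without each array and 100 in both. The estimated correlation ended 143 list calls and added 1. Gene calls lost and gained were 26 and 34 with array weights, 59 and 20 with the compared groups alone, 38 and 7 with the mean of probe sets, 35 and 20 with quantile normalization and 43 and 9 with the signal range covariate. The labels give no animal or replicate number to pair arrays by. As a hint from the data, not the design, arrays at the same place in the order of their groups deviated together between cell types: the mean correlation of deviations from the group means was 0.148, 0.19 and 0.14 at the same place and -0.0366, -0.0469 and -0.0342 at other places for lining cells and osteocytes, osteoblasts and lining cells and osteoblasts and osteocytes, and 53, 61 and 59 of 80 arrays correlated best with their own place. A fit with that place as a replicate block, chosen after seeing the data, called 0, 653 and 450 genes for the response of osteoblasts minus lining cells, osteoblasts minus osteocytes and lining cells minus osteocytes, and 11256, 11496 and 9617 in the same vehicle pairs, and ended no gene or list call. The planned covariate of 3' minus middle signal of control probe sets was not run, since those probe sets are not in the matrix used here. Genes that did not pass the filter on dim signals, such as Sost in the fits of osteoblasts and of lining cells, were not tested there.

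The counts below are genes called by limma where they differ from those of the report by over 1.5 times, and the cause was not tested. Array weights gave 760 (day 8), 16 (day 85), 1148 (day 183), 24 (day 197), 1887 (day 237), 769 (day 309) and 425 (time) in osteoblasts. In lining cells they gave 207 (day 8), 0 (day 85), 242 (day 183), 20 (day 197), 746 (day 267), 724 (day 237), 296 (day 309) and 74 (time). In osteocytes they gave 352 (day 8), 201 (day 29), 67 (day 85), 691 (day 183), 1107 (day 197), 1334 (day 267) and 621 (time). For the response they gave 1 (osteoblasts minus lining cells). The compared groups alone gave 78 (day 8), 1062 (day 29), 61 (day 85), 102 (day 183), 18 (day 197), 27 (day 309) and 24 (time) in osteoblasts. In lining cells they gave 2 (day 8), 2 (day 29), 0 (day 85), 45 (day 183), 2 (day 197), 449 (day 267), 0 (day 309), 24 (dose) and 0 (time). In osteocytes they gave 41 (day 85), 577 (day 183), 393 (day 197), 831 (day 267), 783 (day 237), 1000 (day 309) and 306 (time). The mean of probe sets gave 3 (day 29), 2 (day 197), 83 (day 267), 17 (day 309) and 0 (time) in lining cells. In osteocytes it gave 43 (day 29) and 80 (day 197). No filter gave 4 (day 197) in lining cells. Quantile normalization gave 1134 (day 29), 595 (day 183), 574 (day 309) and 220 (time) in osteoblasts. In lining cells it gave 9 (day 29), 36 (day 85), 32 (day 183), 2 (day 197), 28 (day 267) and 158 (dose). In osteocytes it gave 61 (day 29), 382 (day 183), 42 (day 197) and 118 (day 267). For the response it gave 518 (lining cells minus osteocytes). In vehicle pairs it gave 3967 (osteoblasts minus lining cells) and 7563 (osteoblasts minus osteocytes). The signal range covariate gave 629 (day 8), 191 (day 29), 201 (day 183), 463 (day 237), 0 (day 309), 457 (dose) and 100 (time) in osteoblasts. In lining cells it gave 99 (day 8), 10 (day 29), 52 (day 85), 36 (day 183), 3 (day 197), 37 (day 267) and 211 (dose). In osteocytes it gave 73 (day 29), 21 (day 197) and 131 (day 267). For the response it gave 710 (osteoblasts minus osteocytes). Leaving out arrays of outlying signal range gave 104 (day 85) in osteoblasts. In lining cells it gave 20 (day 8) and 13 (day 183).

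Quantile normalization turned the sign of Lef1 (-0.18), Alpl (-0.24), Mdm2 (-0.0438) and Myc (-0.0205) for osteoblasts minus lining cells, Lef1 (-0.27), Tnfrsf11b (-0.11), Mdm2 (-0.25) and Myc (-0.16) for osteoblasts minus osteocytes, Lef1 (-0.092) and Myc (-0.13) for lining cells minus osteocytes in vehicle, since it removes the shift of all genes. The signal range covariate turned the sign of cell cycle genes (-0.0144) and chondrocyte markers (0.051) in osteoblasts of day 309, and the cause was not tested.

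Leaving out 1 array changed these counts of called genes by over 1.5 times, each given after the count of all arrays. Day 8 osteoblasts (415) had 138 and 206 without vehicle replicates 3 and 5, 188 and 153 without 3 mg/kg replicates 2 and 4, 246 without 50 mg/kg replicate 2, at most 611 otherwise. Day 29 osteoblasts (1713) had 862 and 687 without vehicle replicates 1 and 2, 982 without 3 mg/kg replicate 2, at most 2224 otherwise. Day 85 osteoblasts (201) had 104 without vehicle replicate 4, 125 without 3 mg/kg replicate 5, at most 263 otherwise. Day 183 osteoblasts (375) had 243, 132 and 154 without vehicle replicates 1, 2 and 3, 240 without 3 mg/kg replicate 4, 244 and 671 without 50 mg/kg replicates 4 and 5. Day 197 osteoblasts (9) had 5 and 14 without 3 mg/kg replicates 3 and 5. Day 237 osteoblasts (1222) had 686 without vehicle replicate 4, 695, 801 and 747 without 50 mg/kg replicates 1, 2 and 3, at most 1216 otherwise. Day 309 osteoblasts (1203) had 1833, 144 and 335 without vehicle replicates 1, 3 and 4, 743, 578 and 241 without 50 mg/kg replicates 1, 2 and 3. The 64 of the time contrast in osteoblasts became 23, 211, 17, 36 and 26 without day 8 vehicle replicates 1, 2, 3, 4 and 5, 103 and 24 without day 8 3 mg/kg replicates 1 and 4, 12 and 30 without day 183 vehicle replicates 2 and 3, 42 and 126 without day 183 50 mg/kg replicates 3 and 5. Day 8 lining cells (36) had 6, 4 and 5 without vehicle replicates 1, 2 and 3, 19 and 60 without 3 mg/kg replicates 2 and 4, 20 without 50 mg/kg replicate 3. Day 29 lining cells (5) had 2, 3, 2 and 8 without vehicle replicates 1, 2, 3 and 5. Day 85 lining cells (9) had 17, 1 and 4 without vehicle replicates 2, 3 and 5, 14 without 3 mg/kg replicate 1, 15 without 50 mg/kg replicate 2. Day 183 lining cells (6) had 3, 2, 12 and 0 without vehicle replicates 1, 2, 3 and 4, 3 without 3 mg/kg replicate 2, 12 without 50 mg/kg replicate 1. Day 197 lining cells (7) had 3, 3 and 2 without vehicle replicates 2, 4 and 5, 2, 4 and 1 without 3 mg/kg replicates 1, 2 and 4, at most 10 otherwise. Day 267 lining cells (125) had 9, 81, 191 and 24 without vehicle replicates 1, 2, 3 and 5, 66, 52, 35 and 42 without 3 mg/kg replicates 1, 2, 3 and 5. Day 237 lining cells (168) had 82, 77, 59 and 255 without vehicle replicates 2, 3, 4 and 5, 108 and 101 without 50 mg/kg replicates 3 and 4. Day 309 lining cells (47) had 118, 25, 17 and 28 without vehicle replicates 1, 2, 4 and 5, 133, 123, 11 and 13 without 50 mg/kg replicates 2, 3, 4 and 5. The 75 of the dose contrast in lining cells became 115 without day 29 3 mg/kg replicate 4, 48 without day 85 50 mg/kg replicate 5. The 2 of the time contrast in lining cells became 0, 0, 0, 1 and 4 without day 8 vehicle replicates 1, 2, 3, 4 and 5, 1 and 4 without day 8 3 mg/kg replicates 2 and 4, 1 without day 8 50 mg/kg replicate 2, 1, 0 and 0 without day 183 vehicle replicates 2, 4 and 5, 1 without day 183 3 mg/kg replicate 2, 1, 1 and 1 without day 183 50 mg/kg replicates 1, 3 and 5. Day 8 osteocytes (34) had 11 and 8 without vehicle replicates 1 and 3, 22 without 50 mg/kg replicate 4, at most 38 otherwise. Day 29 osteocytes (25) had 13 and 13 without vehicle replicates 1 and 3, 45, 16 and 42 without 50 mg/kg replicates 1, 3 and 4. Day 183 osteocytes (244) had 138, 99 and 136 without vehicle replicates 2, 3 and 5, at most 263 otherwise. Day 197 osteocytes (132) had 62 and 79 without vehicle replicates 2 and 3, 45 and 74 without 3 mg/kg replicates 2 and 3, at most 144 otherwise. Day 267 osteocytes (431) had 151 without vehicle replicate 5, 197 without 3 mg/kg replicate 1, at most 449 otherwise. Day 309 osteocytes (1941) had 1126 without 50 mg/kg replicate 5, at most 2752 otherwise. The 61 of the time contrast in osteocytes became 24, 26 and 25 without day 8 vehicle replicates 1, 2 and 3, 32, 9 and 24 without day 183 vehicle replicates 2, 3 and 5, 38 without day 183 3 mg/kg replicate 4, at most 81 otherwise. The 0 of the response of osteoblasts minus lining cells became 1 without lining cell day 29 3 mg/kg replicate 3. Leaving out 1 array changed 467 and 114 of 27845 gene values to not called and called.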

Other observations

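Treatment labels were exchanged among the arrays of a cell type and day, or cell type labels among the vehicle arrays of a day, to see how often other splits of the same arrays call as many genes as the real one, which counts among the 100 splits. The results are given with the real count and the highest count of another split in brackets. With 1 of 100 splits as large, no other split called as many genes as the real one in osteoblasts day 8 (415, 127), day 29 (1713, 1704), day 85 (201, 181), day 237 (1222, 544) and dose (289, 232), in lining cells day 183 (6, 5), day 267 (125, 29), day 237 (168, 29), dose (75, 60) and time (2, 1), in osteocytes day 183 (244, 98), day 197 (132, 42), day 267 (431, 147), day 237 (1566, 865), day 309 (1941, 1927), dose (1774, 117) and time (61, 24), for the response osteoblasts minus osteocytes (446, 150) and lining cells minus osteocytes (334, 240), in vehicle pairs osteoblasts minus lining cells (11239, 2178), osteoblasts minus osteocytes (11481, 3360) and lining cells minus osteocytes (9561, 571). It can also be excluded with 2 of 100 splits in osteoblasts day 183 (375, 676), day 197 (9, 15) and time (64, 176), in lining cells day 8 (36, 258) and day 197 (7, 7), in osteocytes day 8 (34, 51) and day 85 (747, 970), and with 4 of 100 in osteoblasts day 309 (1203, 1714). Chance cannot be excluded in lining cells day 29 (5, 494), day 309 (47, 2635) and day 85 (9, 418), with 12, 14 and 42 of 100 splits. Nor can it in osteocytes day 29 (25, 868), with 15 of 100. For the counts of 0 from limma, in osteoblasts day 267 (0, 23), for the response osteoblasts minus lining cells (0, 257), any split calls at least as many (100 of 100 splits), and the splits decide nothing. Over 3 times the real count was called by 1, 8, 17 and 6 splits in lining cells of days 8, 29, 85 and 309, and by 8 in osteocytes of day 29, and the cause was not tested. At unadjusted p under 0.05 the 2 counts of 0 were 388 and 670.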
